A study of Mus musculus with 41 samples.

How the data were processed

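RNA was measured on 41 Illumina arrays from 14 groups: 24 arrays of TEC in 8 groups and 17 arrays of nonTEC in 6 groups. Per the labels' protocols, both fractions were sorted by flow cytometry, RNA was purified with Qiagen RNeasy kits and checked on a Bioanalyzer, and biotin-labelled cRNA was made with the Ambion TotalPrep kit. The deposited values are normalized log2 intensities. The base of the logarithm is not stated and was taken as 2, since the highest values near 15 fit a 16-bit scanner. The arrays of TEC share nearly the same quantiles and so do the arrays of nonTEC, with different quantiles between the fractions, from which it was read that the authors normalized each fraction separately. A probe was present on all arrays of a fraction or on none, so that 21242 probes were present in TEC, 21815 in nonTEC and 18386 in both, of 24671. The submitters' processing notes name limma without a version or a role. The background correction, the detection filter and the scanner software are not given in the sources used here. Array medians were 6.68 in TEC and 6.81 to 6.82 in nonTEC. The lowest correlation between arrays of a group was 0.875 in TEC (middle-aged arrays 2 and 3) and 0.973 in nonTEC, and no pair of arrays was identical. Every array was assigned to its group from the labels and 0 were left out.

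Probes were given the gene listed for them, and the 20825 probes with 1 listed gene were used. Each gene was represented by its probe of highest mean. A gene was tested where the mean of at least 1 group lay above 6.73, the median of all values, which left 8195 of 12176 genes in TEC, 7762 of 11704 in nonTEC and 8487 of 10543 in both. No genome was used, so no positions are given. The values were used as deposited, without further scaling. Group means were fitted in limma 3.58.1 (R 4.3.3) with a mean-variance trend in the empirical Bayes step, within TEC and within nonTEC, and over all 41 arrays for comparisons between the fractions. All 16 comparisons were contrasts of these means, with Benjamini-Hochberg adjustment over the genes tested in each and a threshold of 0.05. Differences between days in TEC were tested over the 3 days together, and the averages over days weigh the days equally. The sham arrays of the same day were the control of each castrated group. Residual degrees of freedom were 16 in TEC, 11 in nonTEC and 27 over all arrays. The 32 gene lists, of cell types, pathways and stress responses, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, for lists with at least 5 members tested, and members were also adjusted over the list alone. The relation between ageing and castration was the slope across genes of the castration difference on the ageing difference, tested by exact two-sided permutation of castrated and sham labels within days. Figures were drawn with Python 3.11.15.

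The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where stated. The rule took the 8 genes of largest change in each direction that passed the threshold and whose groups did not overlap on any array, or, for averages, that had 1 sign on each day, leaving out clone names and uncharacterised loci. It also took up to 4 members past the threshold of each list (the 2 of smallest p where camera passed and no member did), of which the text prints a part, and a fixed set of thymic genes reported in any case where analysed here. For differences between fractions and for sham against unoperated mice it took 5 genes in each direction. The test over days has no direction, and there the 10 genes of smallest p were named.

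On data simulated from the fitted spread, with 200 genes changed, the fit recovered 43% to 94% of log2 changes of 1 and 80% to 100% of changes of 2 across the 16 comparisons. Of changes of 1 the fewest were recovered between days in nonTEC (43%) and TEC (46%) and for the ageing difference between fractions (45%). Of these simulated calls 1.56% to 8.14% were false. They lack structure shared by real arrays, so real rates may differ. The alternatives tried were no filter and a stricter filter on dim probes (the 65th percentile, 7.84), quantile normalization over the arrays, centring each array on its median, the mean of all probes of a gene, array weights, fits without a trend or with a robust trend, a fit of only the arrays compared, a fit of all 41 arrays, a replicate block, other controls (unoperated middle-aged arrays, or sham arrays pooled over days), and leaving out each array in turn. For slopes, only genes past the threshold for ageing were also used. Alternatives added after the data were seen are named in the closing section.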

Results

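Gene expression was measured on Illumina arrays in 2 stromal fractions of the thymus of male C57BL/6 mice. Thymic epithelial cells (TEC) were sorted as CD45-negative EpCAM-positive cells, and the remaining stroma (nonTEC: fibroblasts, endothelium, pericytes and other CD45-negative EpCAM-negative cells) was sorted beside them. CD45 marks leukocytes and EpCAM is an epithelial adhesion molecule, so the gate was set to leave thymocytes out of both fractions. The thymus shrinks with age, and castration of males, which removes most circulating androgen, is followed by its regrowth. The comparisons ask which transcripts differ between young mice of 5 to 6 weeks and middle-aged mice of 9 to 12 months, and which differ between castrated and sham-operated middle-aged mice at day 4, 7 or 20 after surgery. TEC gave 24 arrays in 8 groups of 3. NonTEC gave 17 arrays in 6 groups, of 3 arrays each except sham at day 7 with 2, and day 20 was not analysed here in this fraction. The number of arrays limits the precision. The labels do not say that arrays of a group came from separate animals, so the p-values measure only the spread between these arrays. Differences are log2 values ± SE from limma with adjusted p-values (Benjamini-Hochberg), and group means are log2 values ± SD.

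The 2 fractions carried the transcripts their gates select for. Over the unoperated young and middle-aged arrays, Krt8, a keratin of simple epithelia, was higher in TEC by 4.04 ± 0.19 (13.25 ± 0.26 against 9.21 ± 1.13, n = 6 each). Pdgfra, a fibroblast receptor, was lower in TEC by -6.20 ± 0.38 (6.40 ± 1.11 against 12.60 ± 0.39), and Pecam1, an endothelial adhesion molecule, by -2.83 ± 0.46. Of 8487 genes tested, 2489 were higher and 4021 lower in TEC at an adjusted p under 0.05, with the reservation that TEC and nonTEC arrays were normalized separately before deposit. Epcam was not analysed here. Some arrays stood apart within their group. Array 3 of sham day 4 TEC had higher means over the fibroblast markers (9.00 against 7.08 and 7.16 on the other arrays of its group), the endothelial markers (8.29 against 6.12 and 6.13) and the thymocyte markers (8.94 against 6.47 and 6.55). All 6 day 20 TEC arrays, castrated and sham alike, lay between 0.28 and 0.38 on the first principal component (35.5% of the variance), on which no other TEC array was above 0.017. On the second component (19.6%) middle-aged TEC array 2 lay farthest, at 0.51, and middle-aged TEC array 3 and castrated day 4 TEC arrays 2 and 3 lay on the other side, at -0.43, -0.34 and -0.42. The arrays left out below as standing apart are these last 3 and sham day 4 array 3. Middle-aged TEC array 2, though farthest on the second component, was kept there, a choice made after the data had been seen.

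Ageing in TEC raised transcripts of immediate early factors, Otog, Kl and Bmp4 among other genes, and lowered tissue antigens that depend on Aire, the regulator that lets medullary cells express genes of other tissues. Both group calls, from camera at a preset correlation, were lost with an estimated one (adjusted p = 0.245 and 0.447), as were all others in this comparison. The largest rise was in Otog, which encodes an inner ear membrane glycoprotein, from 6.13 ± 0.26 in young to 10.83 ± 0.85 in middle-aged TEC (4.70 ± 0.38, adjusted p = 4.62e-07). Kl, the co-receptor klotho, rose by 2.69 ± 0.44. The potassium channel gene Kcnk1 rose by 2.57 ± 0.21 (adjusted p = 4.62e-07). The neuroendocrine granule gene Chga rose by 2.53 ± 0.35 and the host transcript of small nucleolar RNAs Snhg11 by 2.52 ± 0.27. The nitric oxide receptor subunit gene Gucy1a1 rose by 2.37 ± 0.25, the ubiquitin ligase gene Trim9 by 2.34 ± 0.32 and the growth factor gene Bmp4 by 2.29 ± 0.37. The largest falls were in Dio1, a thyroid hormone deiodinase, which fell by 2.57 ± 0.59 (adjusted p = 0.00642), and in Reg3g, an antimicrobial lectin, which fell by 2.41 ± 0.73. Serpinb2, a plasminogen activator inhibitor, fell by 2.18 ± 0.38. The homeodomain gene Hopx fell by 2.17 ± 0.69 and Sumo2 fell by 2.13 ± 0.59. The tubulin gene Tuba1a fell by 2.09 ± 0.63. The membrane protease gene Tmprss4 fell by 2.02 ± 0.64 and Gnat3, the gustducin of taste and tuft cells, fell from 8.51 ± 0.53 to 6.51 ± 1.46. In these 16 genes the arrays of the groups did not overlap, as the naming rule required. When the sham arrays averaged over days stood in for the unoperated middle-aged arrays, a comparison chosen after these values were seen, the 8 rises passed. Of the 8 falls only Serpinb2 (-1.18) and Gnat3 (-1.33) passed there. Sumo2 (-0.038), Tuba1a (-0.53), Dio1 (-0.65), Tmprss4 (-0.87), Reg3g (-0.89) and Hopx (-1.47) kept their sign but did not, so these 6 calls rest on the unoperated arrays.

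Of 11 measured Aire-dependent antigens, 7 fell, none rose and 10 fell when adjusted over the list alone (median -1.02, camera adjusted p = 0.000230, and adjusted p = 0.447 with an estimated correlation). Fabp9, a testis fatty acid binding protein gene, fell by 1.54 ± 0.52. The milk casein gene Csn1s1 fell by 1.23 ± 0.38, and the salivary genes Dcpp1 and Dcpp2 fell by 1.09 ± 0.30 and fell by 1.02 ± 0.32. Aire itself was at 11.94 ± 0.52 against 12.18 ± 0.12 (-0.24 ± 0.22, adjusted p = 0.441). Among 19 medullary TEC genes, Tnfrsf11a, the receptor RANK, fell by 1.12 ± 0.36 and Cd40, a receptor that matures medullary cells, fell by 0.64 ± 0.14, with 2 of the list fallen over all genes tested and 1 when adjusted over the list alone (camera adjusted p = 0.0334, and adjusted p = 0.457 with an estimated correlation). Of 14 cortical TEC genes 3 rose: the transcription factor genes Tbx1 (1.55 ± 0.28) and Eya1 (0.84 ± 0.21) and the chemokine gene Cxcl12 (1.49 ± 0.43), which also numbered 3 when adjusted over the list alone, without a set-wide shift (camera adjusted p = 0.0885). Immediate early genes, which answer stimulation and cell handling alike, rose in 8 of 16 members, also 8 when adjusted over the list alone (median 0.53, camera adjusted p = 0.000318, and adjusted p = 0.245 with an estimated correlation). Fosb rose by 1.60 ± 0.27, Klf2 by 1.45 ± 0.38, Zfp36 by 1.31 ± 0.15 and Jun by 1.30 ± 0.21. Markers of other cells moved as well. Among 8 genes of pericytes and smooth muscle 5 fell, Myh11 by -1.10 ± 0.33 and Acta2 by -1.06 ± 0.26, with 7 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 0.00767, and adjusted p = 0.245 with an estimated correlation). Of 7 pan-leukocyte genes 3 fell and 6 when adjusted over the list alone, among them Rac2 (-1.15 ± 0.22) and Cd52 (-0.92 ± 0.27), with camera adjusted p = 0.00128, and adjusted p = 0.245 with an estimated correlation. The haemoglobin gene Hba-a1 fell by 1.58 ± 0.38. Egfr, the epidermal growth factor receptor, rose by 1.12 ± 0.14, and Fgf21, a fibroblast growth factor, fell by 0.87 ± 0.13 from 13.08 ± 0.05 (adjusted p = 0.000321). Socs3, an inhibitor of cytokine signalling, rose by 1.40 ± 0.20, and the iron-binding lipocalin gene Lcn2 by 1.29 ± 0.27.

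In all, 974 genes rose and 553 fell of 8195 tested in ageing TEC, 486 of them by 2-fold or more. The count was 759 without young array 2, 983 without young array 3, 906 without middle-aged array 2, 2392 without middle-aged array 3 and 8 when only the 6 arrays compared were fitted, and it was 2956 when the 4 arrays described as standing apart were left out. With sham in place of unoperated middle-aged arrays it was 2152, with 1037 of the 1527 among them.

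Ageing in nonTEC lowered transcripts of the cell cycle, of thymocytes and of other leukocytes, and raised Ptx3, Wnt10a, Fst and Fgf10. The group calls, from camera at a preset correlation, were lost with an estimated one (adjusted p = 0.452 for the cell cycle, 0.452 for thymocytes and 0.452 for pan-leukocyte genes). The acute-phase pentraxin gene Ptx3 rose by 3.51 ± 0.38 (from 8.04 ± 0.81 to 11.55 ± 0.77, adjusted p = 7.16e-06). The Wnt ligand gene Wnt10a rose by 3.20 ± 0.24 (adjusted p = 2.99e-07). The actin-severing gene Scin rose by 2.63 ± 0.16 and the retinol-oxidising dehydrogenase gene Adh7 by 2.60 ± 0.21. The clock gene Per2 rose by 2.56 ± 0.26 and the aldehyde oxidase gene Aox3 by 2.37 ± 0.25. The Ras exchange factor gene Rasgrf1 rose by 2.32 ± 0.43 and the cation transporter gene Slc47a1 by 2.32 ± 0.25. Spink1, a trypsin inhibitor gene, fell by 4.16 ± 0.40 (adjusted p = 2.68e-06). The precursor B cell gene Vpreb3 fell by 3.92 ± 0.36, and the surrogate light chain genes Igll1 and Vpreb1 fell by 3.87 ± 0.39 and by 3.06 ± 0.36. Pglyrp1, a peptidoglycan receptor gene of granulocytes, fell by 3.48 ± 0.35. The cytochrome gene Cyp2a5 fell by 3.20 ± 0.45. The chitinase-like gene Chil1 fell by 3.13 ± 0.26. The epidermal gene Rptn fell by 3.10 ± 0.32.

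Of 26 cell cycle genes 22 fell and none rose in ageing nonTEC, against 22 fallen and 1 risen when adjusted over the list alone (median -1.40, camera adjusted p = 1.80e-09, and adjusted p = 0.452 with an estimated correlation). Cdk1, the mitotic kinase, fell from 8.70 ± 0.07 to 5.70 ± 0.45. The topoisomerase gene Top2a fell by 2.58 ± 0.43. Thymocyte transcripts fell beside them, 11 of 13 and 12 when adjusted over the list alone (median -1.45, camera adjusted p = 1.58e-05, and adjusted p = 0.452 with an estimated correlation), Cd3e by -1.76 ± 0.39 and Cd3g by -1.85 ± 0.39. All 7 pan-leukocyte genes fell, also 7 when adjusted over the list alone (median -2.26, camera adjusted p = 1.30e-06, and adjusted p = 0.452 with an estimated correlation), with Coro1a at -2.38 ± 0.35. The antigen presentation genes of MHC class II fell in 8 of 9 cases, 9 when adjusted over the list alone (camera adjusted p = 0.000503, and adjusted p = 0.452 with an estimated correlation), Cd74 by -1.63 ± 0.37. Epithelial transcripts were lower in this EpCAM-negative fraction too: Aire fell by 2.26 ± 0.37 to 5.24 ± 0.61. The medullary regulator gene Fezf2 fell by 1.77 ± 0.28 and Krt8 fell by 1.69 ± 0.33. The cortical chemokine gene Ccl25 fell by 1.68 ± 0.42. Of 14 medullary TEC genes 6 fell and 1 rose, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.452 with an estimated correlation). Among 29 matrix genes 12 fell and 3 rose, 13 and 3 when adjusted over the list alone, with the collagens Col1a1 (-1.37 ± 0.21), Col4a1 (-1.22 ± 0.16) and Col4a2 (-1.26 ± 0.17) lower (camera adjusted p = 0.0297, and adjusted p = 0.621 with an estimated correlation). Thy1, a fibroblast surface marker that thymocytes also carry, fell by 0.97 ± 0.12. Fst, the activin antagonist follistatin, rose by 1.48 ± 0.29. The BMP antagonist gene Chrd rose by 1.09 ± 0.16, the Wnt agonist gene Rspo3 by 1.29 ± 0.22, Hgf by 1.15 ± 0.29, Fgf10 by 1.13 ± 0.24 and Fgf7 by 0.77 ± 0.24, both ligands of the epithelial receptor FGFR2b. The metallothionein gene Mt2 rose by 2.18 ± 0.51, and Gpx3, a secreted glutathione peroxidase gene, by 0.74 ± 0.15.

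Of 7762 genes tested in nonTEC, 1308 rose and 1210 fell with ageing, 610 of them by 2-fold or more. The count was 1333 when only the 6 arrays compared were fitted and 840 with each array's mean over the thymocyte list as a covariate. With sham in place of unoperated middle-aged arrays it was 2299, with 1579 of the 2518 among them.

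The ageing effects of the 2 fractions were tested against each other in 1 fit of all 41 arrays, and 953 of 8487 genes differed, 660 with the higher value in TEC. Wnt10a (TEC -0.90, nonTEC 3.20, difference -4.10 ± 0.44), Adh7 (-0.98 and 2.60, difference -3.57 ± 0.47), the B-cell chemokine gene Cxcl13 (-1.83 and 1.60, difference -3.43 ± 0.78), Ptx3 (0.31 and 3.51, difference -3.20 ± 0.56) and the intramembrane protease gene Sppl2a (-1.64 and 1.54, difference -3.18 ± 0.85) had the lower value in TEC. Mzb1, a plasma cell chaperone gene (1.38 and -2.51, difference 3.89 ± 0.64), Vpreb3 (-0.30 and -3.92, difference 3.62 ± 0.48), the chitinase-like gene Chil3 (0.76 and -2.80, difference 3.56 ± 0.85), the clock gene Nr1d1 (1.67 and -1.81, difference 3.49 ± 0.56) and Igll1 (-0.51 and -3.87, difference 3.36 ± 0.48) had the higher. The count was 585 without young TEC array 2, 618 without young nonTEC array 3, 114 when only the arrays compared were fitted, 1557 with sham in place of unoperated middle-aged arrays and 1727 without the TEC arrays that stood apart. In the fits of each fraction 464 genes were called in both, 67 of them in opposite directions, and the ageing differences correlated across 6810 genes at r = 0.29, where genes are not independent replicates.

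At day 4 after castration, TEC carried more ATP6, Ifi47, Pes1 and Tnfaip3 and less Lyz2, Nqo1, Pomc and Cd80 than sham TEC, with single members of many lists changed and few lists shifted. ATP6, the mitochondrially encoded ATP synthase subunit, was at 10.24 ± 0.08 against 6.26 ± 1.05 (3.97 ± 0.86, adjusted p = 0.0234). Ifi47, an interferon-induced GTPase gene, rose by 3.38 ± 0.86. The ribosome assembly gene Pes1 rose by 3.28 ± 0.78 and the NF-kB inhibitor gene Tnfaip3 by 2.59 ± 0.71. The mitochondrially encoded oxidase subunit COX2 rose by 2.25 ± 0.48 and the cornified envelope gene Sprr2a1 by 1.93 ± 0.36. The ATP synthase subunit gene Atp5e rose by 1.91 ± 0.50 and Ankrd46 by 1.91 ± 0.48. Lyz2, the lysozyme of macrophages, fell by 4.09 ± 1.09 (adjusted p = 0.0421), although another probe of the gene had the opposite sign. The quinone reductase gene Nqo1 fell by 2.33 ± 0.64. The kallikrein gene Klk1b27 fell by 2.33 ± 0.62 and Tmem45a fell by 2.31 ± 0.45. The hormone precursor gene Pomc fell by 2.21 ± 0.47. The histone chaperone gene Supt16 fell by 2.16 ± 0.53. The costimulatory ligand gene Cd80 fell by 1.97 ± 0.51. The prohormone-processing gene Cpe fell by 1.81 ± 0.46. Among list members, Pax1, a transcription factor gene of the pharyngeal pouches, rose by 1.56 ± 0.40. The epithelial factor gene Grhl2 rose by 1.33 ± 0.28, the oncostatin M receptor gene Osmr by 1.59 ± 0.42, Mmp9 by 0.78 ± 0.16, Ifit2 by 0.65 ± 0.18 and Fosb by 1.06 ± 0.27, and Hsd17b11, a steroid dehydrogenase gene, fell by 1.71 ± 0.46. Pan-leukocyte genes were lower as a list, with Rac2 the 1 of 7 that fell (-1.03 ± 0.22), also 1 when adjusted over the list alone (camera adjusted p = 0.0466, and adjusted p = 0.729 with an estimated correlation). None of 24 cell cycle genes passed over all genes tested and 2 fell when adjusted over the list alone (median -0.26, camera adjusted p = 0.0466, and adjusted p = 0.729 with an estimated correlation); Aurka was at -0.71 ± 0.20 (adjusted p = 0.0550) and Cdk1 at -1.45 ± 0.44. The limma test called 201 genes higher and 112 lower of 8195. The count was 0 without castrated array 2 (1286 at an unadjusted p under 0.05), 4 without castrated array 3, 1366 without castrated array 1, 490 without sham array 1, 78 without sham array 2 and 34 without sham array 3, and in a fit of only these 6 arrays it was 0 (1473 at an unadjusted p under 0.05), and against unoperated middle-aged TEC it was 1.

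At day 7 after castration, 14 genes passed in TEC, 6 higher and 8 lower, with 1077 at an unadjusted p under 0.05. The replicative helicase gene Mcm6 rose by 1.07 ± 0.21 (8.99 ± 0.11 against 7.92 ± 0.16). The cell cycle factor gene E2f1 rose by 1.06 ± 0.16 (adjusted p = 0.0238). The condensin gene Ncapd2 rose by 1.11 ± 0.21 and the lamin gene Lmnb1 by 0.89 ± 0.18. The splicing gene Wbp11 rose by 0.82 ± 0.16 and the fatty acid desaturase gene Fads1 by 0.62 ± 0.12. Kcnk1, which had risen with age, fell by 1.06 ± 0.21 (adjusted p = 0.0409). The FOXO target gene Depp1 fell by 1.02 ± 0.19. The protease inhibitor gene Serpina5 fell from 7.21 ± 0.21 to 6.21 ± 0.16. The semaphorin gene Sema4b fell by 0.94 ± 0.16 and Ogfod3 fell by 0.74 ± 0.15. The autophagy gene Atg101 fell by 0.73 ± 0.14. The epoxide hydrolase gene Ephx1 fell by 0.72 ± 0.13. The aldehyde dehydrogenase gene Aldh2 fell by 0.68 ± 0.13. Of 24 cell cycle genes 2 rose and 9 when adjusted over the list alone (median 0.47, camera adjusted p = 2.77e-10, and adjusted p = 0.0600 with an estimated correlation). None of 8 pericyte and smooth muscle genes passed over all genes tested and 5 rose when adjusted over the list alone (median 0.73, camera adjusted p = 0.000128, and adjusted p = 0.0600 with an estimated correlation), with Tagln at 1.30 ± 0.27 (adjusted p = 0.0542). Cholesterol synthesis genes were higher as a list with none of 7 past, 2 when adjusted over the list alone (camera adjusted p = 0.00943, and adjusted p = 0.0600 with an estimated correlation), and Lss was at 0.96 ± 0.21 (adjusted p = 0.0588). Tuft cell genes were lower as a list with none of 9 past (camera adjusted p = 0.00943, and adjusted p = 0.684 with an estimated correlation). The count of 14 was 1 or 0 without any 1 of the 6 arrays, 0 with no filter on dim probes, 314 against unoperated middle-aged TEC and 279 without the TEC arrays that stood apart.

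At day 20 after castration, TEC carried more of the medullary and Aire-dependent transcripts and less of the immediate early transcripts and of BMP, activin and TGF-beta pathway transcripts than sham TEC. Of the 7 lists that camera called at a preset correlation 1, the immediate early genes, was also called with an estimated one. Serpinb2 rose by 2.17 ± 0.38. The keratin gene Krt84 rose by 2.14 ± 0.24 (9.40 ± 0.17 against 7.26 ± 0.28, adjusted p = 1.30e-05). The lymphoid coactivator gene Pou2af1 rose by 2.11 ± 0.44 and the antimicrobial ribonuclease gene Ang4 by 2.07 ± 0.27. The galectin gene Lgals7 of stratified epithelia rose by 2.04 ± 0.37, the germ cell gene Dppa3 by 2.04 ± 0.29, and the skin protease genes Klk7 and Asprv1 by 2.03 ± 0.41 and 2.01 ± 0.36. The acute-phase inhibitor gene Serpina3n fell by 2.91 ± 0.28 (adjusted p = 2.62e-06). The tight junction gene Cldn11 fell by 2.72 ± 0.41, Fam107a fell by 2.66 ± 0.31 and Trim9 fell by 2.41 ± 0.32. The placental growth factor gene Pgf fell by 2.31 ± 0.27 and Kcnk1 fell by 2.30 ± 0.21 from 10.17 ± 0.19 (adjusted p = 2.62e-06). The pyruvate dehydrogenase kinase gene Pdk4 fell by 2.19 ± 0.30. The transport adaptor gene Sybu fell by 2.11 ± 0.25.

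Of 11 Aire-dependent antigens 10 rose at day 20 and 11 when adjusted over the list alone (camera adjusted p = 1.72e-07, 0.177 with an estimated correlation), among them Fabp9 (1.76 ± 0.52), the insulin gene Ins2 (1.59 ± 0.33) and Dcpp1 (1.55 ± 0.30). Of 19 medullary TEC genes 7 rose, 10 when adjusted over the list alone (camera adjusted p = 0.000334, 0.180 with an estimated correlation): Aire by 1.07 ± 0.22 from 11.87 ± 0.03, Cd40 by 1.19 ± 0.14 and Cd80 by 1.57 ± 0.51. Cell cycle genes rose in 9 of 24, 11 when adjusted over the list alone (median 0.82, camera adjusted p = 0.000139, 0.180 with an estimated correlation), with the mitotic activator gene Cdc20 at 1.19 ± 0.24 and the replication factor gene E2f2 at 1.23 ± 0.27. The cell cycle inhibitor genes Cdkn1a (0.86 ± 0.16), Cdkn1c (to 12.26 ± 0.13 from 10.76 ± 0.10) and Cdkn2a (1.63 ± 0.38) rose as well, 3 of 12. Immediate early genes fell in 11 of 16 cases and 14 when adjusted over the list alone (median -1.12, camera adjusted p = 1.89e-09, and adjusted p = 0.0405 with an estimated correlation): Atf3 by -1.96 ± 0.22 and Fosb by -1.79 ± 0.27. Of 19 genes of BMP, activin and TGF-beta signalling 7 fell, 10 when adjusted over the list alone (camera adjusted p = 0.00140, 0.177 with an estimated correlation): Fst by -2.10 ± 0.47, and the BMP-induced genes Id1 and Id3 by -1.17 ± 0.16 and -0.91 ± 0.22. In the Notch pathway, Notch3 fell by 1.56 ± 0.22. The target gene Hey1 fell by 0.98 ± 0.23, 4 of 10 having fallen and 1 risen. Fgf21 rose by 1.40 ± 0.13 (adjusted p = 2.62e-06). The RANKL decoy receptor gene Tnfrsf11b rose by 1.41 ± 0.25 and Egfr fell by 0.89 ± 0.14. The steroid-induced genes Fkbp5 and Per1 fell by 0.89 ± 0.14 and 0.89 ± 0.29. Lcn2 fell by 2.05 ± 0.27, Socs3 fell by 1.59 ± 0.20, and the acute-phase gene Saa3 rose by 1.96 ± 0.37. Leukocyte markers were higher beside these groups: 6 of 7 pan-leukocyte genes rose, also 6 when adjusted over the list alone (camera adjusted p = 0.000334, 0.177 with an estimated correlation), with Rac2 at 1.35 ± 0.22 and Cd52 at 1.24 ± 0.27, and 4 of 6 myeloid genes rose, also 4 when adjusted over the list alone (camera adjusted p = 0.00500, 0.177 with an estimated correlation), with Fcer1g at 1.52 ± 0.31.

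At day 20 limma called 1057 genes higher and 761 lower of 8195, 782 of them by 2-fold or more, and leaving out sham array 2 lowered the count to 1169. Against other controls, which mix castration with the shift of all day 20 arrays, the calls moved. From unoperated middle-aged TEC 4177 genes differed (1016 of the 1818). From sham pooled over days 1724 did (718 of the 1818), 622 higher and 1102 lower. Kcnk1 (-2.40 against unoperated, -2.12 against pooled sham), Fst (-2.46 and -2.19), Serpina3n (-2.47 and -2.39), Atf3 (-2.87 and -2.31), Krt84 (1.94 and 1.76) and Aire (1.05 against pooled sham) passed against both, Cd40 (0.80 and 0.58) and Cd80 (1.99 and 0.96) only against the unoperated arrays, and Fgf21 (0.31 and 0.44), Dcpp1 (0.45 and 0.52) and Ins2 (0.46 and 0.46) against neither.

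**Figure D1:**
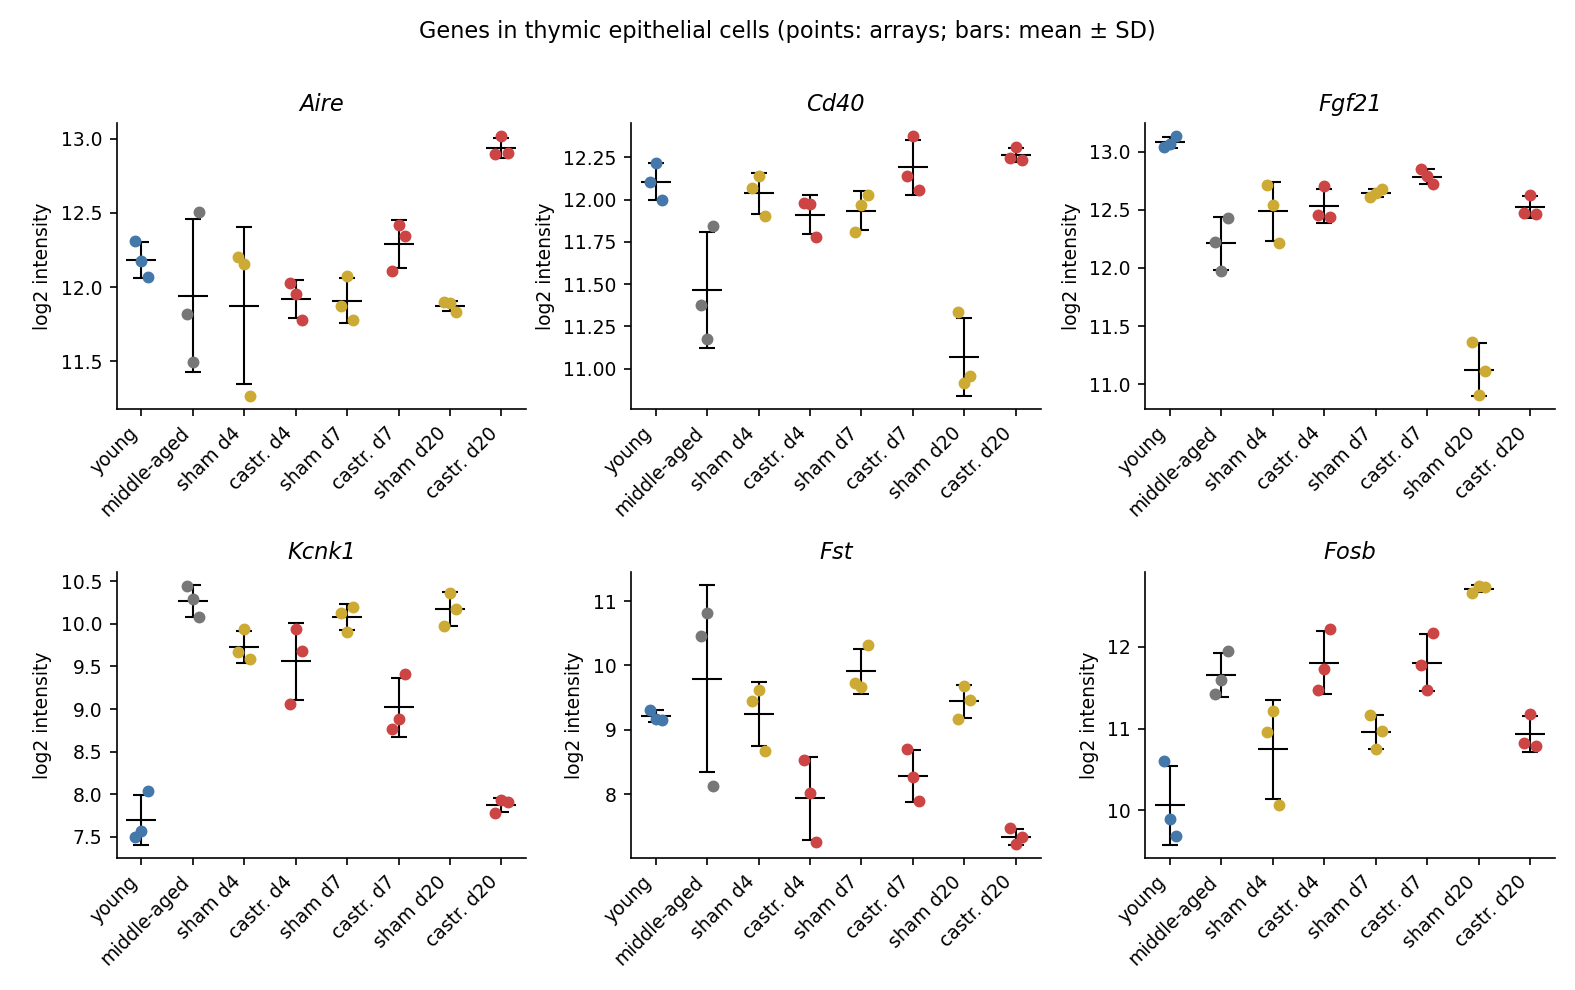
Log2 expression (y axis) of Aire, Cd40, Fgf21, Kcnk1, Fst and Fosb in the 8 TEC groups (x axis: young, middle-aged, and sham and castrated at day 4, 7 and 20); points are arrays and bars the group mean ± SD of 3 arrays. At day 20 the castrated arrays lie above the sham arrays for Aire, Cd40 and Fgf21 and below them for Kcnk1, Fst and Fosb, and sham means at day 20 are lower than at day 4 for Cd40 (11.07 against 12.04) and Fgf21 (11.13 against 12.49).

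Averaged over the 3 days, castration lowered the acute-phase gene Serpina3n in TEC by -1.66 ± 0.16 (adjusted p = 1.51e-05), Fst by -1.68 ± 0.27 and Trim9 by -1.33 ± 0.18. The actin regulator gene Gsn was lower by -1.88 ± 0.47, the cytokine gene Il34 by -1.71 ± 0.34, Nqo1 by -1.54 ± 0.37, Serpinb3d by -1.53 ± 0.21 and the growth factor gene Fgf1 by -1.42 ± 0.42. The neuropeptide gene Grp rose by 1.96 ± 0.57. The fatty acid binding protein gene Fabp5 rose by 1.31 ± 0.36, COX2 by 1.28 ± 0.28, Sltm by 1.21 ± 0.35 and the poly(A)-binding protein gene Pabpc1 by 1.21 ± 0.38. The proline transporter gene Slc6a7 rose by 1.09 ± 0.20, the noncoding Miat by 1.09 ± 0.22 and the endocytosis gene Eps15 by 1.04 ± 0.33. Each of these 16 had 1 sign on all days. Of 19 medullary TEC genes 4 rose and 7 when adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.633 with an estimated correlation): Aire by 0.50 ± 0.12 (1 of its 3 probes had the opposite sign), Cd40 by 0.44 ± 0.08, Fezf2 by 0.41 ± 0.08 and Irf8 by 0.73 ± 0.22. Aire-dependent antigens rose in 1 of 11 cases, Csn1s1 by 0.88 ± 0.22, and in 4 when adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.743 with an estimated correlation). Of 24 cell cycle genes 4 rose and 10 when adjusted over the list alone, with Mcm6 at 0.53 ± 0.12 (1 of its 3 probes had the opposite sign) and E2f1 at 0.51 ± 0.09 (camera adjusted p = 0.000482, and adjusted p = 0.419 with an estimated correlation). Smooth muscle genes rose in 3 of 8 cases, also 3 when adjusted over the list alone, Tagln by 0.94 ± 0.16 and Acta2 by 0.69 ± 0.15 (camera adjusted p = 0.0169, and adjusted p = 0.419 with an estimated correlation). Immediate early genes fell in 4 of 16 cases and 5 when adjusted over the list alone, Ier3 by -0.57 ± 0.11 (camera adjusted p = 0.00796, and adjusted p = 0.419 with an estimated correlation). In all 473 genes rose and 406 fell. The count was 461 and 491 without sham day 20 arrays 2 and 3, 577 and 491 without castrated day 20 arrays 1 and 2, 584 and 1277 without castrated day 4 arrays 3 and 1 and 519 without sham day 7 array 3. It was 1978 against unoperated arrays and 144 against pooled sham.

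The castration effect differed between days for 1386 TEC genes in limma's test over the 3 days. The 10 genes of smallest p went from 1 sign at day 4 to the other at day 20. The kallikrein gene Klk4 was at -0.97, 0.05 and 1.90 at day 4, 7 and 20, the pepsinogen gene Pgc at -0.96, -0.06 and 1.89, the growth factor gene Igf2 at -0.96, -0.28 and 1.62, the sulfotransferase gene Sult1c2 at -1.04, -0.51 and 1.58, the acute-phase gene Orm1 at -1.18, -0.80 and 1.22, Pcp4l1 at -0.87, 0.22 and 1.47, Cytl1 at -0.69, -0.07 and 1.71, and the lipogenic gene Thrsp at -0.74, -0.30 and 1.51. The transporter gene Slc46a2 went the other way, at 0.84, 0.60 and -1.34, as did the RNA demethylase gene Fto at 0.36, 0.01 and -0.87, of which another probe had the opposite sign. Between day 4 and day 20, 107 genes were called on both days and 103 of them had opposite signs. The count over the days was 796 without sham day 20 array 2, 878 without sham day 20 array 3, 845 without castrated day 20 array 1 and 2149 in a fit of only these arrays. In nonTEC the same test between day 4 and 7 called 0 genes, with 798 at an unadjusted p under 0.05, and the count was 2 without castrated day 4 array 3 and 1 without sham day 4 array 1.

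At day 4 after castration, nonTEC carried more transcripts of dividing cells, of thymocytes and of cortical epithelium and less of C7, Hp, Slc47a1 and Agt than sham nonTEC. Of the 14 lists that camera called at a preset correlation none was called with an estimated one. The epithelial secretory gene Wfdc2 rose by 2.71 ± 0.40 (adjusted p = 0.00168, and -0.08 against unoperated arrays). The replication clamp partner gene Pclaf rose by 2.56 ± 0.44 and Cdk1 by 2.33 ± 0.33 from 5.08 ± 0.24. The inhibitory T-cell receptor gene Ctla4 rose by 2.30 ± 0.33, and the replication-dependent histone genes H2ac11, H2ac12, H2ac15 and H2ac21 by 2.62 ± 0.37, 2.41 ± 0.39, 2.36 ± 0.41 and 2.55 ± 0.44; these are near-identical copies whose probes may not tell them apart. The complement gene C7 fell by 2.37 ± 0.30 (8.40 ± 0.38 against 10.77 ± 0.14, adjusted p = 0.000935). The haptoglobin gene Hp fell by 1.98 ± 0.40, and Slc47a1, which had risen with age, fell by 1.95 ± 0.25. The kinase anchor gene Sphkap fell by 1.82 ± 0.27. The calcium sensor gene Hpca fell by 1.67 ± 0.28. The angiopoietin-like gene Angptl7 fell by 1.54 ± 0.43. The angiotensinogen gene Agt fell by 1.54 ± 0.35. The glycosyltransferase gene Galnt17 fell by 1.52 ± 0.31.

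Of 26 cell cycle genes 19 rose at day 4 in nonTEC, 23 when adjusted over the list alone (median 1.52, camera adjusted p = 2.92e-22, and adjusted p = 0.178 with an estimated correlation), with the DNA methylation cofactor gene Uhrf1 at 2.15 ± 0.38. Thymocyte genes rose in 10 of 13 cases, against 11 risen and 1 fallen when adjusted over the list alone (median 1.58, camera adjusted p = 7.51e-11, and adjusted p = 0.178 with an estimated correlation), Cd3d by 2.19 ± 0.37 and Cd3e by 1.94 ± 0.39, and all 7 pan-leukocyte genes rose, also 7 when adjusted over the list alone (camera adjusted p = 1.83e-09, and adjusted p = 0.178 with an estimated correlation). The mean over the thymocyte list was 9.11, 8.23 and 7.34 on the 3 castrated arrays against 6.98, 6.98 and 6.73 on the sham arrays, and the mean over the cell cycle list 8.72, 7.88 and 7.10 against 6.65, 6.74 and 6.64. Of 8 cortical TEC genes 5 rose and 6 when adjusted over the list alone (camera adjusted p = 6.43e-07, and adjusted p = 0.178 with an estimated correlation), Tbata by 2.14 ± 0.41, Krt18 by 1.94 ± 0.32, Krt8 by 1.84 ± 0.33 and Ccl25 by 1.63 ± 0.42. MHC class II genes rose in 2 of 9 cases and 8 when adjusted over the list alone (camera adjusted p = 3.63e-05, and adjusted p = 0.286 with an estimated correlation), and endothelial genes in 2 of 17 and 5 when adjusted over the list alone (camera adjusted p = 0.000557, and adjusted p = 0.286 with an estimated correlation), Flt1, a VEGF receptor, by 1.20 ± 0.31. Matrix genes fell in 6 of 29 cases, against 14 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 0.000126, and adjusted p = 0.286 with an estimated correlation), Mmp2 by -0.56 ± 0.14 and Timp3 by -0.54 ± 0.13. Wnt pathway genes fell in 4 of 15 cases, against 8 fallen and 2 risen when adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.286 with an estimated correlation), Rspo3 by -1.02 ± 0.22, Sfrp1 by -0.95 ± 0.25 and Axin2 by -0.72 ± 0.18. The growth factor genes Fgf10 and Bmp4 fell by 0.83 ± 0.24 and fell by 0.54 ± 0.12 (another Bmp4 probe had the opposite sign), Hmox1 fell by 1.13 ± 0.24 and Gpx3 fell by 0.78 ± 0.15, and the sterol synthesis genes Sqle and Fdps rose by 0.81 ± 0.20 and 0.71 ± 0.17. In all 200 genes rose and 275 fell of 7762. The count was 53 without sham array 3, 58 without castrated array 1, 184 without castrated array 2 and 195 without sham array 2, and it was 0 with the thymocyte list mean as a covariate (503 at an unadjusted p under 0.05).

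**Figure D2:**
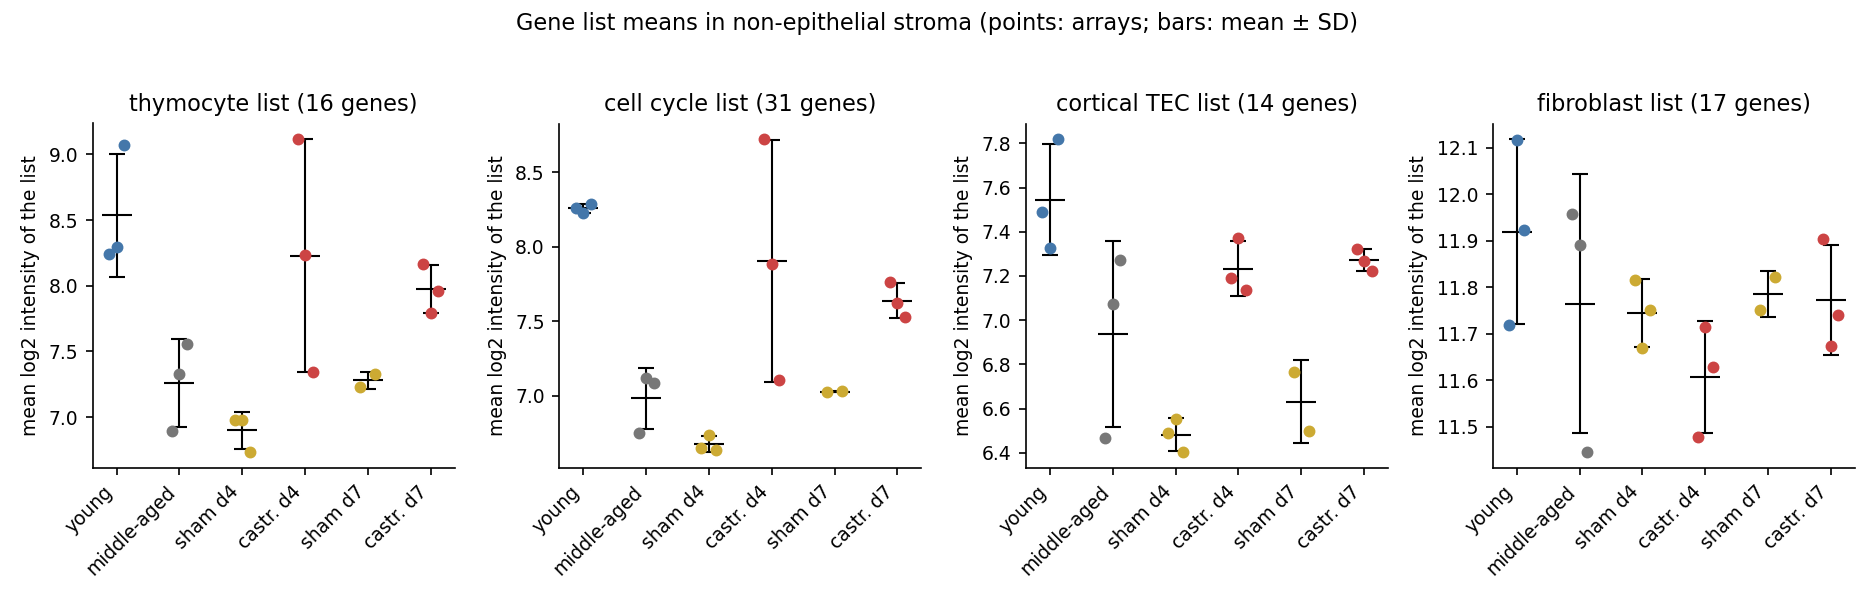
Mean log2 expression over the thymocyte (16 genes), cell cycle (31 genes), cortical TEC (14 genes) and fibroblast (17 genes) marker lists (y axis) in the 6 nonTEC groups (x axis); points are arrays and bars the group mean ± SD of 3 arrays, 2 for sham at day 7. The thymocyte and cell cycle means of the castrated day 4 arrays spread over 7.34 to 9.11 and 7.10 to 8.72, above all sham day 4 arrays.

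At day 7 after castration, C7, Hp, Slc47a1, Hpca and Agt were lower in nonTEC as at day 4, and Slc6a12, Slc6a13, Fst and Klf9 were lower beside them. Hp fell by 2.69 ± 0.45, C7 fell by 2.64 ± 0.34 (8.29 ± 0.34 against 10.93 ± 0.05, adjusted p = 0.00100), Slc47a1 fell by 2.29 ± 0.28 and Hpca fell by 2.25 ± 0.32. The GABA and betaine transporter genes Slc6a13 and Slc6a12 fell by 2.08 ± 0.37 and fell by 1.86 ± 0.40, Agt fell by 2.06 ± 0.39, and Fst fell by 1.86 ± 0.32 (adjusted p = 0.0119). The glucocorticoid-induced factor gene Klf9 fell by 0.97 ± 0.13 and Gpx3 fell by 1.18 ± 0.16. The 4 genes that rose were the sperm channel gene Catsperz (2.16 ± 0.41), the thymus LIM protein gene Crip3 (2.03 ± 0.43), the gelatinase gene Mmp9 (0.85 ± 0.17) and the cyclin gene Ccnd1 (0.81 ± 0.15). Lists moved with few or no members past over all genes tested. None of 8 cortical TEC genes passed and 5 rose when adjusted over the list alone (median 1.06, camera adjusted p = 0.000343, and adjusted p = 0.244 with an estimated correlation), with Krt18 at 1.26 ± 0.36. None of 26 cell cycle genes passed and 2 rose when adjusted over the list alone (median 0.70, camera adjusted p = 1.10e-06, and adjusted p = 0.454 with an estimated correlation), and none of 13 thymocyte genes did (median 0.78, camera adjusted p = 4.77e-05, and adjusted p = 0.391 with an estimated correlation). Immediate early genes were lower as a list with none of 16 past (median -0.33, camera adjusted p = 4.57e-05, and adjusted p = 0.284 with an estimated correlation). Cholesterol synthesis genes were higher, 3 of 7 when adjusted over the list alone (camera adjusted p = 0.000112, and adjusted p = 0.0572 with an estimated correlation), with Fdps at 0.88 ± 0.19 (adjusted p = 0.0513). Of 34 genes past the threshold 30 were lower and 4 higher. The count was 0 without sham array 2 and at most 11 without any other 1 of the 5 arrays, and it was 988 against unoperated middle-aged nonTEC and 5 with the thymocyte list mean as a covariate.

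Averaged over both days in nonTEC, C7 fell by 2.51 ± 0.23 (adjusted p = 6.50e-06), Slc47a1 fell by 2.12 ± 0.19 (adjusted p = 6.50e-06), Hp fell by 2.33 ± 0.30, Hpca fell by 1.96 ± 0.21, Agt fell by 1.80 ± 0.26, Angptl7 fell by 1.80 ± 0.32 and Slc6a13 fell by 1.58 ± 0.25. The calpain gene Capn6 fell by 1.42 ± 0.24. Tbata rose by 1.83 ± 0.31, Crip3 by 1.82 ± 0.29 and Cdk1 by 1.79 ± 0.25. The mitotic kinase gene Pbk rose by 1.78 ± 0.24, the small GTPase gene Diras2 by 1.64 ± 0.25, Pclaf by 1.63 ± 0.33, Krt18 by 1.60 ± 0.24 and Catsperz by 1.58 ± 0.27. Of 19 BMP, activin and TGF-beta genes 4 fell, the ligands Bmp7 by -0.85 ± 0.18 and Bmp4 by -0.47 ± 0.09 and the antagonists Fst by -1.32 ± 0.22 and Chrd by -0.57 ± 0.12, against 4 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 0.00911, and adjusted p = 0.155 with an estimated correlation). Rspo3 fell by 0.95 ± 0.16 and Fgf10 fell by 0.83 ± 0.18, Wnt2 rose by 0.71 ± 0.17, and Fgf7 at -0.38 ± 0.18 and Inhba at -0.04 ± 0.24 did not pass (adjusted p = 0.253 and 0.955). Klf9 fell by 0.59 ± 0.08 and Gpx3 fell by 0.98 ± 0.11. The matrix genes Fn1 and Lox fell by 1.06 ± 0.28 and fell by 0.89 ± 0.24, while Sqle and Fdps rose by 0.81 ± 0.15 and 0.80 ± 0.13. Of 26 cell cycle genes 19 rose, 21 when adjusted over the list alone (camera adjusted p = 1.35e-20, and adjusted p = 0.119 with an estimated correlation), of 13 thymocyte genes 11, 12 when adjusted over the list alone (camera adjusted p = 1.32e-11, and adjusted p = 0.119 with an estimated correlation), and of 8 cortical TEC genes 5, 6 when adjusted over the list alone (camera adjusted p = 2.13e-07, and adjusted p = 0.0951 with an estimated correlation). In all 207 genes rose and 289 fell. The count was 153 without sham day 7 array 2, 184 without sham day 7 array 1, 294 without sham day 4 array 3 and 311 without castrated day 4 array 1, and it was 2 with the thymocyte list mean as a covariate, C7 (-2.02) and Slc47a1 (-2.11).

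**Figure D3:**
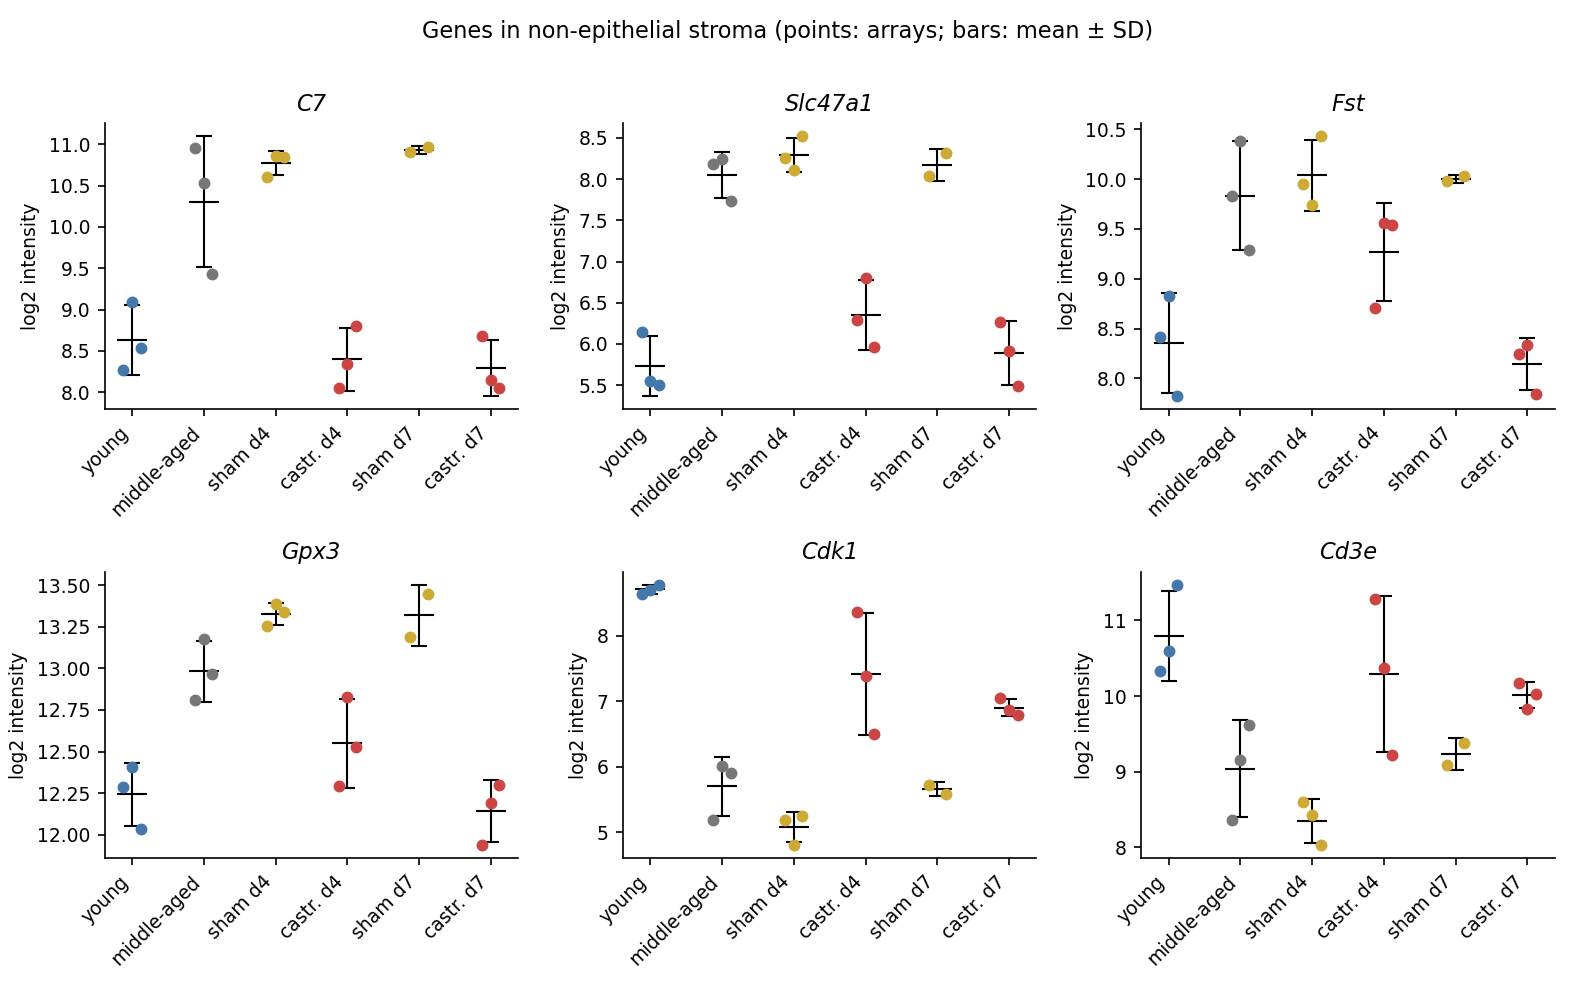
Log2 expression (y axis) of C7, Slc47a1, Fst, Gpx3, Cdk1 and Cd3e in the 6 nonTEC groups (x axis: young, middle-aged, and sham and castrated at day 4 and 7); points are arrays and bars the group mean ± SD of 3 arrays, 2 for sham at day 7. C7 and Slc47a1 lie lower in the castrated than in the sham arrays on both days.

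The castration effects of the 2 fractions, averaged over day 4 and 7, differed for 513 genes of 8487, 312 with the higher value in TEC. Angptl7 (TEC 0.22, nonTEC -1.80, difference 2.02 ± 0.37), the sulfotransferase gene Sult5a1 (0.64, -1.23, 1.87 ± 0.41), Hpca (-0.09, -1.96, 1.86 ± 0.27), Per2 (0.58, -1.21, 1.79 ± 0.30) and Capn6 (0.33, -1.42, 1.75 ± 0.29) had the higher value in TEC. The reductase gene Akr1c12 (-2.37 and 0.26, difference -2.63 ± 0.71), the histone-binding gene Rbbp7 (-2.41 and 0.19, difference -2.60 ± 0.79), the chromatin gene Hmgb2 (-1.55 and 0.92, difference -2.47 ± 0.63) and the RNA-binding genes Hnrnpk (-2.16 and 0.31, difference -2.47 ± 0.73) and Hnrnpa2b1 (-2.13 and 0.27, difference -2.40 ± 0.72) had the lower. With arrays centred on their median the share of higher values was 49.0% in place of 60.8%. The count was 214 and 233 without nonTEC sham day 7 arrays 2 and 1 and 328 without nonTEC castrated day 4 array 1. It was 317 and 1105 without TEC castrated day 4 arrays 2 and 1, and 290 without the TEC arrays that stood apart.

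Most genes that passed in both comparisons moved one way with age and the other after castration in TEC at day 20 and in nonTEC on both days. These comparisons share no arrays. In TEC, 837 genes were called both for ageing and for day 20, and 835 of them had opposite signs (683 of 688, 515 of 518 and 1368 of 1370 without middle-aged arrays 1, 2 and 3): 441 rose with age and fell after castration and 394 fell and rose (90.4 and 71.3 for independent lists). Kcnk1 (ageing 2.57, day 20 -2.30), Trim9 (2.34 and -2.41), Socs3 (1.40 and -1.59), Lcn2 (1.29 and -2.05), Fgf21 (-0.87 and 1.40) and Serpinb2 (-2.18 and 2.17) were among them. At day 4 in TEC 95 of 105 genes called in both had the same sign and 10 opposite signs (124 of 128, 153 of 162 and 182 of 298 with the same sign without middle-aged arrays 1, 2 and 3, of which array 3 stood apart as castrated day 4 arrays 2 and 3 did). At day 7 all 5 had opposite signs (9 of 13, 15 of 16 and 28 of 31 without those arrays in turn). In nonTEC, 341 of 352 genes called for ageing and for castration averaged over days had opposite signs. By direction they were 178 and 163 (48.7 and 32.3 for independent lists). At day 4 it was 248 of 281, at day 7 31 of 32. Slc47a1 (2.32 and -2.12) and Fst (1.48 and -1.32) rose with age, Cdk1 and Cd3e fell. A part from carried-over thymocytes was not separated. The slope across genes of the castration difference averaged over days on the ageing difference was -0.28 in nonTEC, at the smallest p its 200 labellings can give (exact two-sided permutation p = 0.005). In TEC it was -0.19 (exact permutation p = 0.0973 over 8000 labellings), from 0.16 at day 4 (p = 0.3, and 0.18, 0.49 and -0.13 without middle-aged arrays 1, 2 and 3, p = 0.3, 0.2 and 0.3) through -0.09 at day 7 (p = 0.5) to -0.65 at day 20 (p = 0.1, the smallest that the 20 exact labellings of 1 day allow). Without middle-aged arrays 1, 2 and 3 the TEC slope was -0.11, -0.017 and -0.28 (exact permutation p = 0.277, 0.897 and 0.0015), and without the 4 TEC arrays that stood apart it was -0.23 (p = 0.0175).

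**Figure D4:**
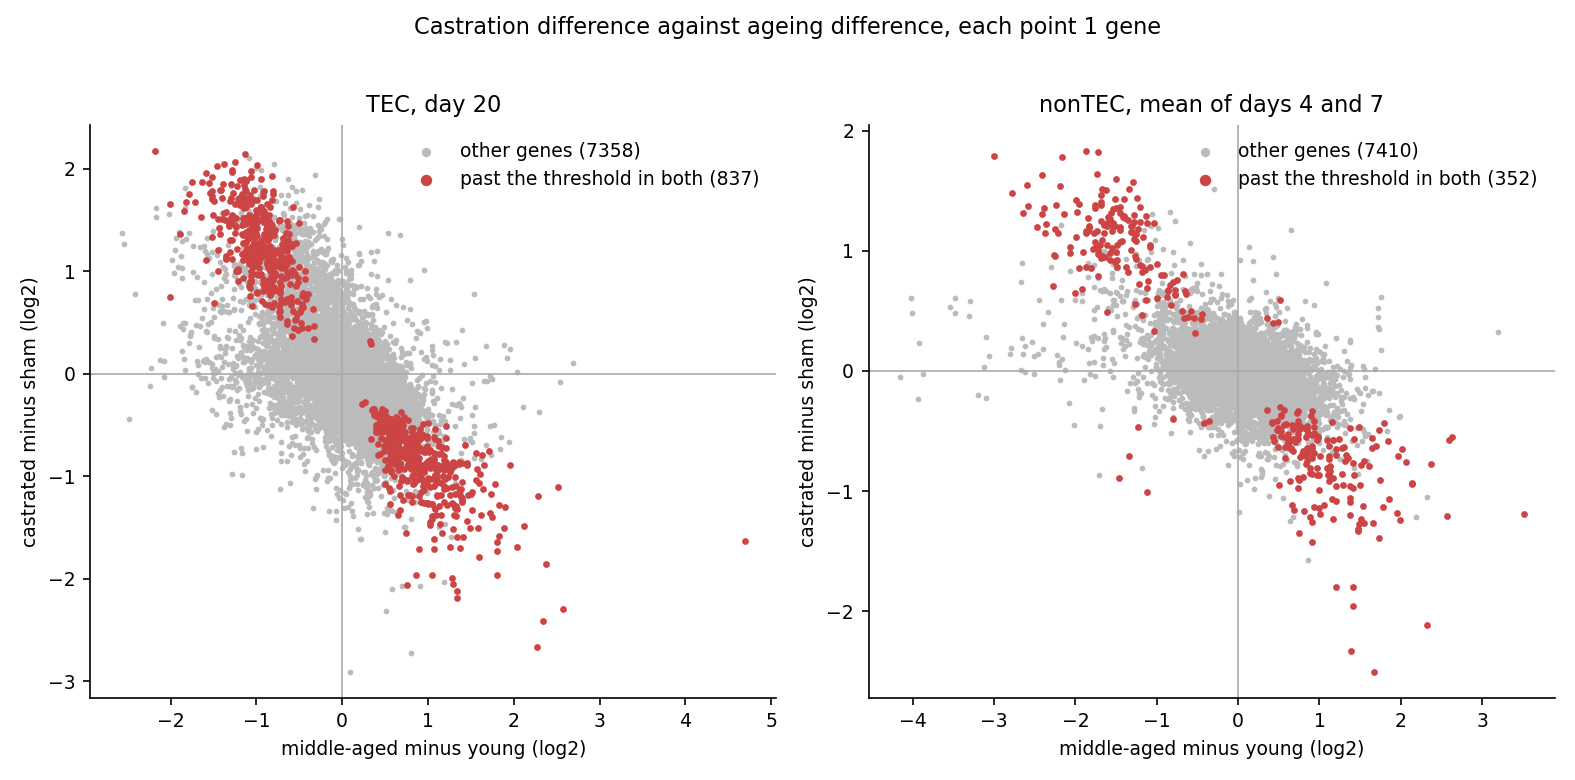
Castration minus sham log2 difference (y axis) against middle-aged minus young log2 difference (x axis), 1 point per gene tested, for TEC at day 20 and nonTEC averaged over days; red points are the 837 (TEC) and 352 (nonTEC) genes past the threshold in both comparisons, of which 835 and 341 lie in the quadrants of opposite sign.

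Some genes were fixed to be reported whatever the test gave. Aire in TEC was at 0.04 ± 0.22 at day 4 and 0.38 ± 0.22 at day 7 (adjusted p = 0.917 and 0.457). Bmp4 in TEC, higher with age, was at -0.09 ± 0.37, -0.63 ± 0.37 and -0.37 ± 0.37 at day 4, 7 and 20, none past the threshold, and Fst at -1.31 ± 0.47 (adjusted p = 0.102) and -1.62 ± 0.47 (adjusted p = 0.167) before its fall at day 20, with 0.59 ± 0.47 for ageing. Psmb11, the cortical proteasome subunit gene, was at 0.96 ± 0.54 for ageing and -1.24 ± 0.54, 0.63 ± 0.54 and -0.20 ± 0.54 over the days, and Ccl25 at -0.55 ± 0.39, 0.15 ± 0.39, 0.27 ± 0.39 and 0.21 ± 0.39. Cd80 was at -1.41 ± 0.51 with age (adjusted p = 0.0582) and -0.69 ± 0.51 at day 7. Cdkn2a, a senescence-associated inhibitor gene, fell by 1.12 ± 0.38 with age in TEC and was at 0.33 ± 0.38 and 0.23 ± 0.38 at day 4 and 7, and the adipocyte gene Adipoq was at -0.84 ± 0.29 with age, -0.71 ± 0.29, -0.21 ± 0.29 and 1.17 ± 0.29. In nonTEC, Bmp4 was at 0.12 ± 0.12 for ageing and -0.40 ± 0.13 at day 7, Fst at -0.77 ± 0.29 at day 4, Inhba, an activin subunit gene, at 0.05 ± 0.32, 0.70 ± 0.32 and -0.78 ± 0.36, Fgf7 at -0.48 ± 0.24 and -0.28 ± 0.26, Fgf10 at -0.84 ± 0.26, Ccl25 at 1.29 ± 0.47, Aire at 0.36 ± 0.37 and 1.57 ± 0.41, and Cdkn2a at -0.12 ± 0.23, 0.70 ± 0.23 and 0.46 ± 0.25. Averaged over days, Cdkn2a rose in TEC by 0.73 ± 0.22 (another probe had the opposite sign) and Ccl25, Aire and Cdkn2a rose in nonTEC by 1.46 ± 0.31, 0.96 ± 0.27 and 0.58 ± 0.17, while in TEC Psmb11 at -0.27 ± 0.31, Ccl25 at 0.21 ± 0.23, Cd80 at -0.36 ± 0.29, Bmp4 at -0.36 ± 0.21 and Adipoq at 0.08 ± 0.17 did not pass. In TEC 1 probe had the opposite sign for Aire and Cdkn2a at day 4 and 7 and for Ccl25 at day 4, and in nonTEC for Cdkn2a in ageing. Foxn1, the master regulator gene of TEC, was too dim to be tested, with group means of 4.74 to 5.81 in TEC, as were Dll4 (5.28 to 6.01), Inhba (4.82 to 5.54), Fgf7 (4.82 to 5.57) and Fgf10 (4.93 to 6.71) in TEC, and Psmb11 (4.71 to 5.23), Dll4 (4.87 to 5.33), Cd80 (4.95 to 5.53) and Adipoq (4.86 to 6.12) in nonTEC. Mki67 was not analysed here, nor Foxn1 in nonTEC.

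Sham-operated TEC over the 3 days differed from unoperated middle-aged TEC in 461 genes, 156 higher and 305 lower. The modifier gene Sumo2 (2.09 ± 0.48), the phosphate carrier gene Slc25a3 (2.06 ± 0.55), the chaperonin gene Tcp1 (1.96 ± 0.27), Dio1 (1.92 ± 0.48) and the chaperone gene Dnajb9 (1.86 ± 0.52) were higher in sham, and the exosome gene Exosc2 (-1.51 ± 0.24), Chga (-1.22 ± 0.28, with another probe of the gene at the opposite sign), Tspan6 (10.89 ± 1.46 against 11.89 ± 0.66), Rc3h2 (6.73 ± 0.68 against 7.73 ± 0.43) and Palm (-0.99 ± 0.27) lower. The count was 112 without middle-aged array 2, 1168 without array 1 and 770 without array 3 of that group. It was 285 and 701 without sham day 4 arrays 1 and 3, and 285, 277 and 275 without sham day 20 arrays 1, 2 and 3. In nonTEC 19 genes were higher in sham, led by the DNA repair gene Paxx (1.32 ± 0.22), Ptms (1.18 ± 0.18), Mustn1 (0.93 ± 0.19), Vps72 (0.92 ± 0.18) and Acox3 (0.90 ± 0.18), and 4 were lower: Wfdc2 (-1.87 ± 0.36), Vps37b (-0.83 ± 0.16), Ypel5 (-0.73 ± 0.14) and the basal epithelial gene Trp63 (-0.72 ± 0.14). The nonTEC count was 9, 123 and 364 without middle-aged arrays 1, 2 and 3, 0, 6 and 2 without sham day 4 arrays 1, 2 and 3, and 0 and 1 without sham day 7 arrays 1 and 2 (1378 and 1197 at an unadjusted p under 0.05 where limma called 0).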

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

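The tests on cell carry-over, dilution, array quality and handling given here were chosen after the results were seen, and the counts over other splits of the arrays were planned before, though the groups that each split left whole were looked at after. The results listed are those whose effects differed between the 2 fractions or between days by a test of the difference itself.

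The ageing effect differed between TEC and nonTEC for 953 genes. Of the 100 splits drawn, 10 gave as many, the real one included, with 1975 as the highest other. The other 9 each left the young and middle-aged arrays of 1 fraction grouped as they were, and so kept its whole ageing effect, while the 77 splits that regrouped both fractions gave at most 276. The share of splits as large therefore says nothing on chance here. The differences, TEC minus nonTEC, were 3.89 for Mzb1, 3.62 for Vpreb3, 3.56 for Chil3, 3.49 for Nr1d1 and 3.36 for Igll1, and -4.10 for Wnt10a, -3.57 for Adh7, -3.43 for Cxcl13, -3.20 for Ptx3 and -3.18 for Sppl2a. The castration effect differed between the fractions for 513 genes. Of 100 splits 1 gave as many, the real one, with 140 as the highest other. The differences were 2.02 for Angptl7, 1.87 for Sult5a1, 1.86 for Hpca, 1.79 for Per2 and 1.75 for Capn6, and -2.63 for Akr1c12, -2.60 for Rbbp7, -2.47 for Hmgb2, -2.47 for Hnrnpk and -2.40 for Hnrnpa2b1. The castration effect in TEC differed between days for 1386 genes, and 1 of 100 splits gave as many, the real one, while the highest other gave 1158 with the day 20 arrays grouped as they were. Day 20 minus day 4 was 2.86 for Klk4, 2.40 for Cytl1, -2.18 for Slc46a2, 2.62 for Sult1c2, -1.22 for Fto, 2.26 for Thrsp, 2.85 for Pgc, 2.40 for Orm1, 2.34 for Pcp4l1 and 2.58 for Igf2. No group held 4 or more arrays, so no single array was tested against its group.

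With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many genes in each case: 1527 for ageing in TEC (highest other 163), 2518 for ageing in nonTEC (13), 313, 14 and 1818 for TEC at day 4, 7 and 20 (112, 0 and 0) and 475 for nonTEC at day 4 (0). For castration averaged over days in TEC (879), 2 of 100 splits were as large. The other (1330) left the day 4 and day 20 arrays grouped as they were. In nonTEC (496) 1 of 100 was, highest other 82. Splits that left no day whole gave 0 in both. For TEC against nonTEC (6510) 1 of 100 was, highest other 5371. Chance was not excluded for sham against unoperated nonTEC (23, 2 of 100, highest other 23, with the same unoperated arrays). Nor was it for sham against unoperated TEC (461, 5 of 100). There the highest other split called 2140, which points to a structure of the arrays. That split put sham day 20 arrays 2 and 3 in place of unoperated ones, as did 2 of the 3 others as large. Whether day 20 is the source was not tested.

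Castrated nonTEC carried more thymocyte, pan-leukocyte and cell cycle transcripts and less of C7, Hp, Slc47a1 and other single genes than sham nonTEC. The list calls were lost with an estimated correlation (adjusted p = 0.119 for each averaged over days), and at day 7 limma called 0 members of these 3 lists over all genes tested (13 of 46 at an unadjusted p under 0.05). Thymocytes carried through the CD45-negative sort are a candidate source of the rise: after removal of group means the cell cycle list followed the thymocyte list over the 17 arrays (r = 0.885, permutation p = 0.00423, adjusted over 4 relations 0.00846; rho = 0.777, permutation p = 0.00545, adjusted 0.0109; r = 0.614 without castrated day 4 arrays 1 and 3). Of the other 3 relations, the pan-leukocyte list followed the thymocyte list (r = 0.948, adjusted 0.00176; rho = 0.936, adjusted 0.00136). Cortical TEC genes followed it by rank (r = 0.493, adjusted 0.0813; rho = 0.664, adjusted 0.0355; r = 0.792 without those 2 arrays) as they did the cell cycle list (r = 0.265, adjusted 0.248; rho = 0.598, adjusted 0.0355; r = 0.758), so epithelial markers, which thymocytes would not bring, moved with them. The gate on CD45 would remove thymocytes, and Ptprc, which encodes CD45, had group means of 4.42 to 5.14 and Cd3e of 8.35 to 10.8, levels of different probes that decide nothing here. With the thymocyte covariate 0 of the 8 genes of largest rise stayed past the threshold (median 1.71 before, 0.98 after) and 2 of the 8 of largest fall (median -1.88 before, -1.48 after), so the lost calls do not set the rises apart. Dilution of stromal RNA by other cells was not decided by the 8 genes of largest fall, which were picked for falling. Their median was -1.88, their smallest fall -1.42. The fibroblast list had a median of -0.13 (95% bootstrap interval -0.29 to -0.0071, 16 members). With the covariate C7 was at -2.02 ± 0.30 (adjusted p = 0.00964, the highest over its alternatives, the lowest 2.12e-09) and Slc47a1 at -2.11 ± 0.28 (adjusted p = 0.00496, likewise the highest, the lowest 2.53e-08), and a response of stromal cells to androgen loss stays open as untested.

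The genes called at day 4 in TEC may reflect a component of array quality. Across all genes the day 4 difference followed the deviation of middle-aged array 3 from the other 2 of its group (r = 0.645 over genes, which are not independent replicates; -0.29 to 0.41 for 12 other arrays). Middle-aged array 2 lay farthest on the other side of that component and its deviation gave r = -0.52, and against array 1 alone that of array 3 gave r = 0.593. Of the 313 genes called, 75.1% had the sign of the deviation of array 3. Castrated day 4 arrays 2 and 3 lay apart on the component on which that array did. The slope of the day 4 difference on the ageing difference, which holds array 3, was 0.16 with all arrays and -0.13 without it, so their agreement depends on that array. An effect of castration at day 4 stays open beside it, as untested.

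Of 837 genes called for ageing in TEC and at day 20 after castration, 835 moved in opposite directions. A single middle-aged array is argued against as the source of the day 20 slope, which was -0.47, -0.55 and -0.56 without middle-aged arrays 1, 2 and 3 and -0.65 with all, although the slope averaged over days was -0.017 without array 2. Handling stress and leukocytes carried through the sort stay open, since genes were picked after removal of group means, which hides differences between whole groups. Over 3367 genes that did not follow the immediate early list the slope was -0.70, with 382 of 383 genes called in both comparisons opposite. It was -0.61 over 768 that followed the list. Over 2737 that did not follow the pan-leukocyte list it was -0.57 (262 of 263). Over 1549 that did it was -0.91, and 3 of the 7 members fell with age and 6 rose at day 20. All day 20 arrays lay together on the first principal component, apart from all other TEC arrays, so a batch of day 20 was not separated from the day, although castrated and sham arrays of that day share it. A return of TEC towards the young state by day 20 remains a hypothesis, found and tested on the same data.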

How the results depend on the processing

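The alternatives that left out arrays standing apart, took the thymocyte list mean as a covariate, put sham in place of unoperated middle-aged arrays, fitted slopes for each day, with and without single middle-aged arrays, or left leukocyte and cell cycle genes out of slopes were chosen after the data were seen, and the others were planned. Every count kept within 1.5 times its value under quantile normalization (except TEC day 7, 28), median centring, a fit without a trend and a robust trend. The count of TEC against nonTEC did so under all 11 alternatives (5306 to 7485). For the other counts the values outside that range follow, and the cause was not tested except where fewer arrays or residual degrees of freedom enter by construction.

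With array weights limma called 2144 genes for TEC day 4, 1790 for day 7, 4262 for day 20 and 3154 averaged, 1512, 626 and 1489 for nonTEC day 4, day 7 and averaged, 2664 for the castration difference between fractions, 4850 for that between days in TEC and 423 in nonTEC, and 54 and 41 for sham against unoperated TEC and nonTEC. The weights were estimated gene by gene, a method taken after the default had not converged and after counts of both had been seen. With only the compared arrays the counts were 8 for ageing in TEC, 1333 in nonTEC and 114 for their difference, 0 (1473 at an unadjusted p under 0.05), 48, 4208 and 1857 for TEC day 4, 7, 20 and averaged, 423 and 756 for nonTEC day 7 and averaged, 2149 and 2 for differences between days in TEC and nonTEC, and 5 and 2 for sham. In 1 fit of all 41 arrays they were 983 and 52 for TEC day 4 and 7, 292 for nonTEC day 4, 2 for days in nonTEC, and 1049 and 101 for sham. Against unoperated arrays they were 1, 314, 4177 and 1978 for TEC day 4, 7, 20 and averaged, and 815, 988 and 904 for nonTEC day 4, 7 and averaged. Against pooled sham they were 16 for TEC day 4, 144 for TEC averaged, 949 for nonTEC day 4 and 451 for day 7. With the arrays that stood apart left out, the counts were 2956 for ageing in TEC, 1727 for its difference from nonTEC, 0 (823 unadjusted) and 279 for TEC day 4 and 7, 290 for the castration difference and 1288 for sham TEC; only 1 castrated array was then left at day 4, which was assumed to vary like the other groups. With sham in place of unoperated middle-aged arrays the ageing difference gave 1557. With the thymocyte covariate the counts were 840 for ageing in nonTEC, 530 and 65 for TEC day 4 and 7, and 0 (503 unadjusted), 5 and 2 for nonTEC day 4, 7 and averaged. The stricter filter gave 206 for TEC day 4, no filter 0 for TEC day 7 (1370 unadjusted) and 11 for sham nonTEC, and the mean of probes 36 for sham nonTEC. With a replicate block the counts were 22 for nonTEC day 7, and 715 and 41 for sham TEC and nonTEC. The block effects were made to sum to 0 within each fraction, a coding taken after a first one had left TEC against nonTEC dependent on the replicate used as reference. Arrays of the same replicate number correlated at -0.15 to 0.26 after removal of group means, and the numbers were not taken as pairs.

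Leaving out 1 array in turn gave 759 to 2392 for ageing in TEC, 1733 to 2737 in nonTEC and 585 to 1298 for their difference, 0 to 1366, 0 to 1, 1169 to 1557 and 461 to 1277 for TEC day 4, 7, 20 and averaged, 53 to 668, 0 to 11 and 153 to 608 for nonTEC day 4, 7 and averaged, 214 to 1105 for the castration difference, 796 to 1874 and 0 to 2 for days in TEC and nonTEC, 112 to 1168 and 0 to 364 for sham, and 6352 to 6512 for TEC against nonTEC. The slope in TEC went from -0.28 to -0.017 and that in nonTEC from -0.29 to -0.25. By day the slope was 0.16 at day 4 in TEC, reversed, and -0.32 and -0.24 at day 4 and 7 in nonTEC, where too few labellings exist to pass 0.05. In TEC it was -0.23 without the arrays that stood apart. Of 78 calls of list tests 1 remained with an estimated correlation.

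Of the values of single genes named, 6888 of 8183 kept their sign and their side of the threshold, 1150 lost the threshold, 89 passed it and 56 reversed, of which 1 passed it, Cdkn2a with the mean of probes (adjusted p = 0.0276, from there to 0.962 over its alternatives). With array weights the reversed values were 0.11 for Cdkn2a and -0.17 for Inhba in ageing nonTEC, and -0.19 for Aire and 0.52 for Bmp4 in TEC day 4. With the mean of probes Aire was -0.48, Ccl25 -0.12 and Cdkn2a -0.77 in TEC day 4, and Cdkn2a -0.083 in day 7. Against unoperated arrays Adipoq was 0.12, Aire -0.021, Aurka 0.43, Cdk1 0.072 and Ifit2 -0.030 in TEC day 4, Adipoq 0.26 and Cd80 0.71 in day 7, Psmb11 0.61 in day 20, Cd80 0.66 and Psmb11 0.075 in TEC averaged, Wfdc2 -0.075 in nonTEC day 4 and Inhba 0.0062 in nonTEC averaged. Against pooled sham Aurka was 0.14 and Bmp4 0.33 in TEC day 4, Adipoq 0.026, Ccl25 -0.024 and Psmb11 -0.089 in day 7 and Psmb11 0.27 in day 20. Without the arrays that stood apart Aire was -0.15, Bmp4 0.055, Cdk1 0.11 and Psmb11 0.37 in TEC day 4, and Adipoq -0.026, Cd80 0.064 and Psmb11 0.27 in TEC averaged. With the thymocyte covariate Inhba was -0.52 in ageing nonTEC, Aire -0.20, Fgf7 0.21 and Fst 0.018 in nonTEC day 4 Fgf7 0.074 in day 7, and Fgf7 0.14 and Inhba 0.41 averaged, and with quantile normalization Aire was -0.0065 in nonTEC day 4. With sham in place of unoperated middle-aged arrays Ccl25 was 0.12 in ageing TEC and Cdkn2a 0.16 in ageing nonTEC. Leaving out 1 array in turn reversed Ccl25 in ageing TEC (-1.002 to 0.24), Cdkn2a (-0.29 to 0.20) and Inhba (-0.12 to 0.32) in ageing nonTEC, Inhba (-0.20 to 0.18) in nonTEC averaged, and Aire (-0.26 to 0.21) and Bmp4 (-0.42 to 0.55) in TEC day 4. Signal over background limits dim genes, since a gene whose group means all lay below 6.73 was not tested.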

Other observations

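Of clock genes some passed in nonTEC, in a list written after Per2 and Nr1d1 had been seen and given no test as a set. With age in nonTEC the repressor gene Per2 rose by 2.56 ± 0.26 and the repressor gene Nr1d1 fell by 1.81 ± 0.31, 2 of 6 that passed of 10 clock genes tested. At day 4 after castration 3 of 10 passed in nonTEC, Per2 at -1.49 ± 0.26, Nr1d1 at 1.65 ± 0.31 and Cry2 at -0.95 ± 0.20, and at day 7 limma called 0 of 10 (2 at an unadjusted p under 0.05). In TEC 2 of 11 passed with age, Nr1d1 at 1.67 ± 0.45 and Per1 at 0.87 ± 0.29, and 2 of 11 at day 20, Per1 at -0.89 ± 0.29 and Clock at -0.55 ± 0.19. The time of day of killing is not given in the sources used here.

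Members of other lists passed in these comparisons. With age in nonTEC the heat shock genes rose in 4 of 10 cases, also 4 when adjusted over the list alone, Hsph1 by 1.05 ± 0.22 and Bag3 by 0.66 ± 0.14, without a set-wide shift (camera adjusted p = 0.0646, and adjusted p = 0.621 with an estimated correlation). Sex steroid and glucocorticoid responsive genes rose in 5 of 12 cases there, also 5 when adjusted over the list alone (camera adjusted p = 0.0717), and after castration averaged over days 1 of 12 fell, 2 when adjusted over the list alone (camera adjusted p = 0.00912, and adjusted p = 0.0951 with an estimated correlation). The haemoglobin and other erythroid genes in TEC fell in 3 of 4 cases with age and rose in 3 of 4 at day 20, and B cell genes rose in 3 of 3 at day 20, lists too short for the set test. Endoplasmic reticulum folding genes in ageing TEC fell in 2 of 11 cases, 3 when adjusted over the list alone (camera adjusted p = 0.0359, and adjusted p = 0.332 with an estimated correlation), Creld2 by -0.72 ± 0.18 and Trib3 by -1.06 ± 0.27. In ageing TEC the matrix genes rose in 8 of 24 cases and fell in 1, 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0885), Timp2 by 1.12 ± 0.16, Bgn by 1.20 ± 0.41 and Lamc1 by 1.12 ± 0.32.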
